A study of Mus musculus with 6 samples.

How the data were processed

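RNA abundance was measured by RNA sequencing in 6 libraries of mouse 32D cells, a myeloid progenitor line kept in interleukin 3 (1 ng/mL, per the labels). The cells carried dCas9-KRAB, a Cas9 protein that cannot cut DNA fused to a repressor domain. They were transduced with lentivirus carrying an empty vector (EV, 2 libraries), guide sg2 (2 libraries) or guide sg5 (2 libraries) and kept in puromycin for a week, per the labels' protocols. Libraries were made with a TruSeq RNA kit and sequenced on an Illumina instrument, per the labels' protocols. Guide sequences and target positions are not given in the sources used here.

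The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library size) per library, with 47606 genes in each. The submitters' processing notes name kallisto 0.43.0, DESeq2 and the mouse builds GRCm38 and mm10, without saying which tool made which values. The annotation release and the step that turned kallisto estimates into FPKM are not given in the sources used here. The deposited position column placed 100% of its entries on chromosome 1, and the deposited strand was that of the annotation for 49.9% of matched genes. Neither column was used here. Positions and gene types come from GENCODE M21 (GRCm38), matched by gene ID for 47187 genes. Symbols are those of the files, and 2124 IDs carry another symbol in GENCODE M21.

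Depth was estimated from the lowest FPKM values of 752 single-transcript genes longer than 4000 nt, taking an assumed fragment length of 200 nt. Values lay near whole multiples of what 1 fragment is worth. Between 92.2% and 97.9% of the low values were whole within a tolerance of 0.15 fragments. The implied depth, rounded, was 32200000 and 45600000 fragments for EV replicates 1 and 2, 39500000 and 38100000 for sg2, and 31800000 and 39100000 for sg5. For a transcript of 1 kb effective length, 3 fragments correspond to between 0.0659 and 0.0944 FPKM, which covers counting error only. For short RNAs a single fragment is worth far more, so their values move in large steps.

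Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 12929 of the 26126 genes above 0 in at least 1 library. Values were taken as log2(FPKM + 1), and every fold change below is on that scale, which understates changes of low genes. The test was limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment, at a threshold of 0.05. The guides were tested as 1 group of 4 libraries against the 2 EV libraries. A fit with 3 groups gave sg2 against EV, sg5 against EV and sg5 against sg2. Count models were not run because the files hold FPKM and not counts. Tables were prepared and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

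Gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry stand beside it. All but the mitochondrially encoded list had members above the filter, and that list was not analysed here. The rule for named genes was also fixed before the data were examined. It took the genes past the threshold whose guide and EV libraries did not overlap, up to 12 in each direction, and up to 5 in each direction for the other comparisons. Where none passed, it took the 5 genes of smallest p. It added the measured neighbours of Cebpe and up to 4 genes of smallest p from each list. Genes named outside that rule are said to be so.

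The replicate numbers of the labels were checked for pairing before the fits were compared. The differences between replicates 1 and 2 correlated across genes between groups, at 0.611 for EV and sg2, 0.591 for EV and sg5, and 0.583 for sg2 and sg5. The first principal component, with 55.8% of the variance, separated the numbers, and 6 of 6 libraries correlated best with a library of the same number. The numbers were therefore treated as pairing the libraries, a reading that comes from the data, since the labels do not call the number a batch or a day. The planned test has no block, and the fit with the replicate number as a block is given where it changes a call. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

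The library titled as the second sg5 replicate has a source name and genotype that name sg2. It was counted as sg5 by its title. The test of both guides together does not depend on this choice.

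The procedure was tested on simulated data with the replicate structure of these libraries. The changed genes were drawn only from those with a mean above about 5 FPKM, and each was moved alike in every guide library. Recovery of lower genes was not measured. For guides against EV over 12929 genes, the test without a block recovered 27 of 100 genes changed by 1 log2 unit and 88 of 100 changed by 3. With the block it recovered 80 and 100, with 13 false calls. For guides against EV over 10581 protein-coding genes with the block, it recovered 78 of 91 and 92 of 92, with 9 false calls. For sg2 or sg5 alone against EV, the test recovered 0 of 100 genes changed by 1 log2 unit without the block and 48 with it. No difference between the guides was simulated. A simulated list lowered by 0.6 log2 units had a camera p of 9.46e-49 without the block, while 3 of 100 random lists had p under 0.05. The simulated genes varied independently of each other, so this does not test the preset correlation on lists whose members vary together. In these data the estimated correlation was 0.0988 for specific granule genes and 0.401 for replication histones. For DNA replication genes it was 0.782 without the block and 0.143 with it. With an estimated correlation, camera also takes its p from the residual degrees of freedom, 4 for guides against EV and 3 with the block. A call lost with an estimated correlation therefore does not by itself show that the members vary together.

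Other settings chosen before the data were examined were other pseudocounts, filters, scalings, thresholds, no trend, the replicate block, each library left out in turn, 3 groups in place of 2, the other reading of the conflicting label, and other list tests. Added after seeing the data were protein-coding genes only, the same with the replicate block, the block without each library in turn or with the other reading of the conflicting label, list tests after quantile normalization, and further settings for the correlation between guides, with 1 that has no library in common.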

Results

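Transcript abundance was compared between 32D cells with dCas9-KRAB and a guide (sg2 or sg5, 2 libraries each) and cells with dCas9-KRAB and an empty vector (EV, 2 libraries). The series title names an enhancer of CEBPE, a transcription factor of late granulocyte development, and its design text sets EV against the sg2 and sg5 knock-down. The libraries hold between 31800000 and 45600000 implied fragments. Each lists between 21239 and 21867 genes above 0.

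Cebpe (ENSMUSG00000052435, GRCm38 chromosome 14, 54710360 to 54712174, minus strand) had lower values in all 4 guide libraries than in both EV libraries. It measured 42.0 and 100 FPKM in EV replicates 1 and 2. It measured 14.4 and 18.7 FPKM with sg2, and 19.4 and 22.7 FPKM with sg5. The guide mean of 18.8 ± 3.39 FPKM (SD, n = 4) was 26.4% of the EV mean of 71.2 ± 41.3 FPKM (SD, n = 2). Against the EV library of the same number, sg2 stood at 34.3% and 18.6%, and sg5 at 46.2% and 22.6%. The log2 difference was -1.75 (SE 0.36), with a limma p of 0.00253 and an adjusted p of 1.00 over all genes. Adjusted over the list alone, the 28 measured genes of the Cebpe region, limma gave 0.0710, and 0.0137 with the replicate block. An exact two-sided permutation test gave p = 0.0667, the smallest that 15 splits of the libraries allow. Permuting within replicate numbers, a test chosen after seeing the data, gave a two-sided p of 0.111, the smallest that its 9 splits allow.

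The neighbours of Cebpe showed smaller differences. 1700123O20Rik, 19.6 kb away, measured 21.6 and 26.6 FPKM in EV and between 12.1 and 17.8 FPKM with guides (log2 difference -0.65, SE 0.19). Acin1, which encodes a chromatin condensation factor, 23.4 kb away, measured 129 and 134 FPKM in EV and between 114 and 122 FPKM with guides (log2 difference -0.16, SE 0.11). Slc7a8, an amino acid transporter gene 10 kb away, measured 15.6 and 50.1 FPKM in EV and between 12.6 and 23.4 FPKM with guides. Its log2 difference was -0.06 within replicate number 1 and -1.08 within number 2, and without EV replicate 2 the value was 0.24 (-0.06 with the replicate block). Slc7a7, a related transporter gene 292.6 kb away, had a log2 difference of 0.27 (SE 0.25), which was -0.15 without EV replicate 1 (-0.04 with the block). None of the 28 genes passed the limma test over all genes, and 15 had negative and 13 positive log2 differences. The region list as a whole had a camera adjusted p of 0.158.

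**Figure D1:**
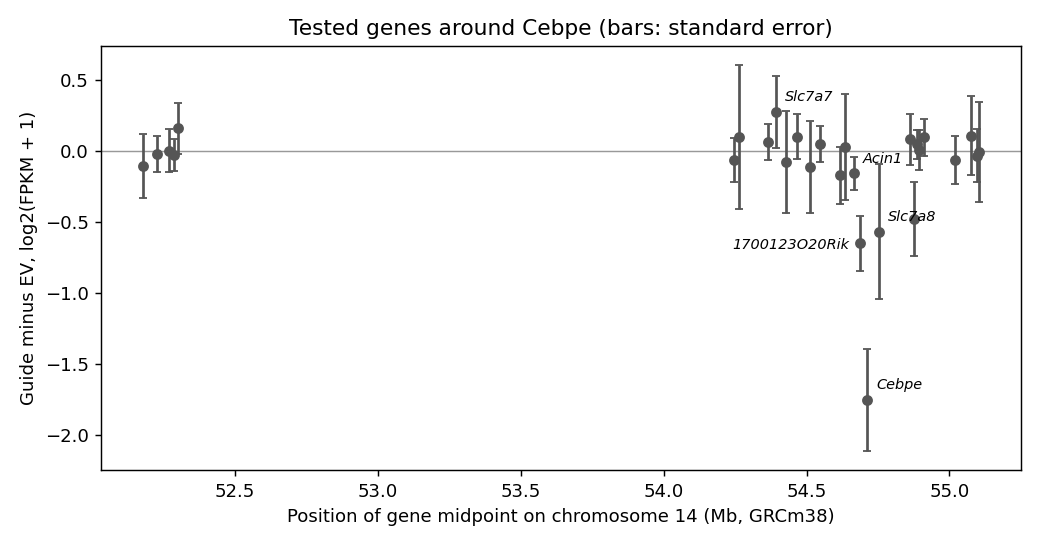
Log2 difference between guide and EV libraries, on the log2(FPKM + 1) scale, for the 28 tested genes of the Cebpe region list, against the midpoint of each gene on chromosome 14 (Mb, GRCm38). Points are limma estimates and bars their standard errors; Cebpe lies lowest at -1.75.

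The 5 genes of smallest p between guide and EV libraries were S100a9, S100a8, Nmral1 and 2 predicted genes. S100a9 and S100a8, which encode the calprotectin subunits of neutrophils, measured 114 ± 22.2 and 41.3 ± 12.9 FPKM in EV (SD, n = 2) against 2.63 ± 1.21 and 1.90 ± 0.90 FPKM with guides (SD, n = 4). Their log2 differences were -5.05 (SE 0.35) and -3.89 (SE 0.34). Nmral1, which encodes an NADPH sensor protein, measured 6.54 and 4.43 FPKM in EV and between 29.7 and 56.4 FPKM with guides (log2 difference 2.70, SE 0.30). The predicted genes Gm23416 and Gm9797 were listed at 0 in all 4 guide libraries and between 3.94 and 7.49 FPKM in EV. None of the 5 passed the limma test without a block, where the smallest adjusted p was 0.0811 for S100a9. The count past the threshold was 0 of 12929 genes, with 169 (1.31%) at an unadjusted p under 0.05, against 739 (5.72%) with the replicate block. In the self-test 0.841% of unchanged genes had a p under 0.05 without the block and 5.44% with it. The test without a block is therefore strict, and its lack of calls is weak evidence of no difference.

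With the replicate block, limma called 5 genes. S100a9 (adjusted p = 0.0445), Ltf (0.0310), Alas1 (0.0310) and Gm23416 (0.0445) fell, and Nmral1 (0.00654) rose. Ltf encodes lactoferrin of specific granules, and Alas1 encodes the first enzyme of heme synthesis, which measured 117 and 160 FPKM in EV and 51.8 ± 3.78 FPKM with guides (SD, n = 4). In the blocked fit 0 genes passed without EV replicate 1, EV replicate 2, sg2 replicate 2 or sg5 replicate 2. Without sg2 replicate 1, S100a9 and Nmral1 passed, and without sg5 replicate 1, Nmral1 and 1 predicted gene that is not among the 5. Restricted to protein-coding genes, a choice made after seeing the data, the blocked fit called 18 genes, 4 higher and 14 lower, with Cebpe among them (adjusted p = 0.0181).

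**Figure D2:**
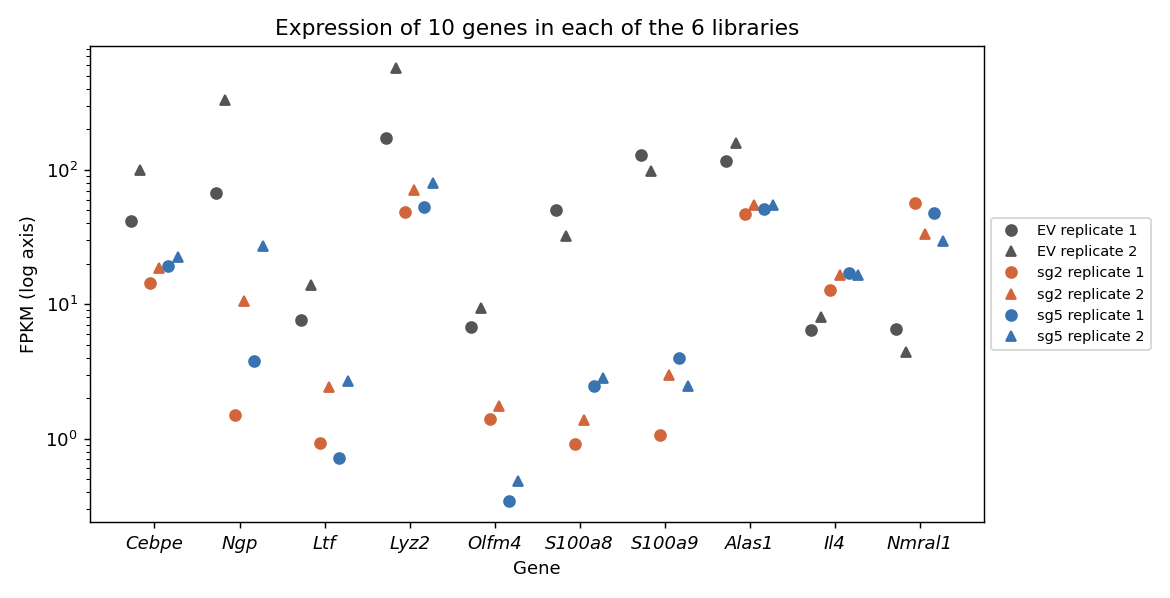
FPKM (log axis) of 10 genes in each of the 6 libraries, with color for the group and marker shape for the replicate number. Cebpe, Ngp, Ltf, Lyz2, Olfm4, S100a8, S100a9 and Alas1 lie lower, and Il4 and Nmral1 higher, in all 4 guide libraries than in both EV libraries.

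Genes of neutrophil specific granules were lower in the guide libraries as a group. All 15 measured members had negative log2 differences, with a median of -0.56. Adjusted over the list alone, limma called 4 of them lower, and 0 adjusted over all genes. Ngp, which encodes neutrophilic granule protein, measured 67.7 and 331 FPKM in EV and between 1.51 and 27.0 FPKM with guides. Ltf measured 7.67 and 13.9 FPKM in EV and 1.70 ± 1.02 FPKM with guides (SD, n = 4). Lyz2, the gene of myeloid lysozyme, measured 173 and 578 FPKM in EV and 63.0 ± 14.7 FPKM with guides (SD, n = 4). Olfm4, a gene of a granule glycoprotein, measured 6.80 and 9.40 FPKM in EV and between 0.35 and 1.75 FPKM with guides. With the replicate block 8 members passed adjusted over the list alone, the others being Lcn2, Hp, Chil1 and Ltb4r1. These 4 lie outside the rule for named genes. The list's camera adjusted p was 2.13e-18, but the adjusted p was 0.0713 with an estimated correlation and 0.298 with that and the block. The median was -0.23 within replicate number 1 and -0.90 within number 2.

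Neutrophil receptor, migration and oxidase genes followed less evenly. Adjusted over the list alone, S100a9 and S100a8 fell among 34 measured members, and 0 passed over all genes. With the replicate block S100a9 passed over all genes, and 4 members fell and 2 rose adjusted over the list alone. The 2 that rose, Csf2rb and Csf2rb2, near-identical cytokine receptor genes and thus uncertain, lie outside the rule for named genes. Their log2 differences were 0.41 (SE 0.42) and 0.50 (SE 0.50), and without EV replicate 2 -0.09 and -0.07, or 0.36 and 0.49 with the block. Gm5483 and Stfa1, genes of the stefin family whose reads cannot be told apart with certainty from near-identical copies, measured 7.42 ± 0.12 and 3.17 ± 0.29 FPKM in EV (SD, n = 2) against 1.04 ± 1.51 and 0.65 ± 0.57 FPKM with guides (SD, n = 4) and fell adjusted over the list alone with the block (limma adjusted p = 0.0467 for both). The camera adjusted p was 7.58e-05, and the adjusted p was 0.138 with an estimated correlation. Without EV replicate 2 the camera adjusted p was 0.313, and the list median was 0.03 within replicate number 1 and -0.19 within number 2. Primary granule genes of promyelocytes had a median of 0.02 over 23 measured members, with 0 called and a camera adjusted p of 0.818.

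Mitotic genes and replication-dependent histone genes were higher as groups. All 51 measured mitotic genes had positive log2 differences with a median of 0.15, and 0 passed alone. Cdc25c, which encodes a phosphatase for entry into mitosis, measured 13.8 ± 0.57 FPKM in EV (SD, n = 2) and 17.3 ± 1.98 FPKM with guides (SD, n = 4), and Cdca8, a gene of the chromosomal passenger complex, 115 ± 4.86 and 131 ± 4.48 FPKM. All 25 measured histone genes had positive log2 differences with a median of 0.60, which was 0.23 within replicate number 1 and 1.01 within number 2. Hist1h4i and Hist1h1a, histone genes with near-identical copies and thus uncertain, measured 5.91 ± 2.14 and 0.97 ± 0.52 FPKM in EV (SD, n = 2) and 11.6 ± 2.83 and 3.21 ± 1.14 FPKM with guides (SD, n = 4). These transcripts lack poly(A) tails. Their median was 0.11 with sg2 and 0.27 with sg5 in number 1, and 1.18 and 0.91 in number 2. Genes under 200 nt held 6.77% of the summed FPKM in EV, 9.03% with sg2 and 9.67% with sg5 in number 1, and 16.4%, 21.5% and 15.4% in number 2. The camera adjusted p was 1.72e-12 for mitosis and 3.73e-16 for histones. With an estimated correlation the adjusted p was 0.0713 and 0.282. Fry gave mitosis an adjusted p of 0.0821 for both guides together and 0.0827 for sg2. For sg5 mitosis passed fry without the block (adjusted p = 0.0355) but not with it (0.0518).

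For both guides together, genes of ribosome biogenesis and ribosomal proteins were lower, and glycolysis and hypoxia genes higher, with the preset correlation alone. Of 50 ribosome biogenesis genes 49 had negative log2 differences (median -0.21), though the median was -0.38 within replicate number 1 and -0.03 within number 2. Polr1b, a subunit of RNA polymerase I, measured 7.62 ± 1.02 FPKM in EV (SD, n = 2) and 5.48 ± 0.59 FPKM with guides (SD, n = 4). Of 61 ribosomal protein genes 60 had negative values, with a median of -0.07. Of 31 glycolysis and hypoxia genes 29 had positive values (median 0.23), and the median was 0.04 within number 1 and 0.42 within number 2. Ero1l, which encodes an oxidase of the endoplasmic reticulum, measured 197 and 78.5 FPKM in EV and between 197 and 323 FPKM with guides, and Ndrg1, a hypoxia-responsive gene, 54.9 and 45.3 against 56.0 to 112 FPKM. The camera adjusted p was 3.62e-07, 0.00590 and 5.32e-06 for these lists. With an estimated correlation the adjusted p was 0.794, 0.868 and 0.658. Camera with the preset correlation gave a difference between the guides for ribosome biogenesis and glycolysis. The ribosome biogenesis median was -0.09 with sg2 and -0.33 with sg5, and that of glycolysis 0.17 and 0.31 (camera adjusted p between guides 0.000162 and 0.0343). With an estimated correlation the adjusted p between guides was 0.980 for both, and 1 of the sg5 libraries has conflicting labels. Ribosomal proteins passed with sg5 (camera adjusted p = 0.00321), and with sg2 only with the block (0.297, and 0.0213 with it). Between guides they also passed only with the block (0.131, and 0.000383 with it). Camera with an estimated correlation gave an adjusted p of 0.813 for sg5 and, with the block, 0.737 for sg2. Fry passed for sg2 with the block (adjusted p = 0.0120). Without EV replicate 1 the ribosome biogenesis list turned to higher in the guides and passed (camera adjusted p = 0.0139), and the ribosomal protein list turned to higher without passing (0.458). Neither turned without that library in the fit with the replicate block, and ribosomal proteins passed as lower (0.00222) while ribosome biogenesis did not pass (0.454). Without EV replicate 2 the glycolysis list turned to lower without passing (0.348), and with the block it stayed higher without passing (0.441).

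Genes of mast cells, basophils and eosinophils had values on both sides of EV. Il4, a cytokine gene, rose adjusted over the list alone (limma adjusted p = 0.0180), from 7.25 ± 1.15 FPKM in EV (SD, n = 2) to 15.7 ± 1.96 FPKM with guides (SD, n = 4). Cyp11a1, a steroid synthesis gene expressed in mast cells, measured 246 ± 8.49 against 346 ± 64.2 FPKM. Epx, the eosinophil peroxidase gene, measured 75.5 and 253 FPKM in EV and between 8.77 and 61.6 FPKM with guides. Prss34, a basophil protease gene outside the rule for named genes, also rose with the replicate block adjusted over the list alone (log2 difference 1.55, SE 1.88 without the block). Without EV replicate 1 its value was -0.30, and 2.03 with the block. The 23 measured members had a median of 0.22, a camera adjusted p of 0.00303 and an adjusted p of 0.658 with an estimated correlation. The median was 0.09 with sg2 (camera adjusted p = 0.308) and 0.27 with sg5 (1.96e-05), and the difference between guides passed (0.000511). With an estimated correlation neither call held (camera adjusted p = 0.584 for sg5 and 0.980 between guides). Without EV replicate 1 the camera adjusted p was 0.993. Inflammatory genes of the NF-kB list had a median of 0.10 over 29 members, with Tnfaip3, a feedback inhibitor, at 31.3 ± 0.33 FPKM in EV (SD, n = 2) and 40.5 ± 4.30 FPKM with guides (SD, n = 4). With an estimated correlation, which was 0.00169 for the NF-kB list and thus below the preset 0.01, the adjusted p was 0.282. That list's camera adjusted p with the preset correlation was 0.0379. Without EV replicate 2 it was 0.636.

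**Figure D3:**
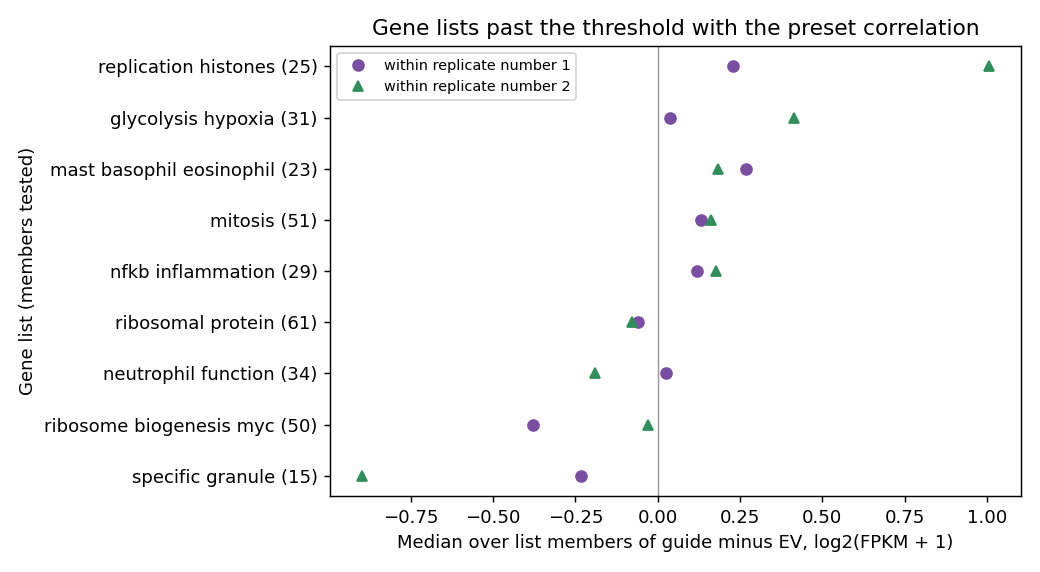
Median log2 difference between guide and EV libraries, on the log2(FPKM + 1) scale, within each replicate number for the 9 gene lists past the threshold with the preset correlation. Numbers of tested members stand in brackets. Specific granule genes lie at -0.23 and -0.90, and replication histones at 0.23 and 1.01.

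In other lists single genes passed adjusted over the list alone. Alas1 did so without the block (limma adjusted p = 0.00268) among 18 heme and iron genes. With the block, Gfi1, a transcription factor gene of granulocyte development, fell (limma adjusted p = 0.0193 among 55 myeloid transcription factors) together with Cebpe (0.0193). Gfi1 measured 8.07 ± 1.08 FPKM in EV (SD, n = 2) and 4.38 ± 0.26 FPKM with guides (SD, n = 4). Among 45 interferon-stimulated genes, Ifi27l2a rose (0.0297) and Oas1a fell (0.0391) in the blocked limma fit. Among 4 nuclear RNAs, Rmrp and Neat1 rose (0.0406 for both) in the blocked limma fit, with log2 differences of 0.78 (SE 0.27) and 0.21 (SE 0.57) without the block, and Neat1 had -0.43 without EV replicate 1 (0.22 with the block). Gfi1 also fell (0.0267) in the blocked limma fit among 38 genes that follow cytokine signals. Myc, among these 38 genes, measured 27.8 ± 9.46 FPKM in EV (SD, n = 2) and 18.3 ± 5.80 FPKM with guides (SD, n = 4) and did not pass. Camera without the block gave no call for the remaining lists. Its adjusted p was 0.333 for myeloid transcription factors, 0.478 for monocyte and for lymphoid markers, 0.665 for MHC class II, and 0.858 for erythroid, stem cell and apoptosis genes. It was 0.304 for cytokine targets, 0.103 for DNA replication, 0.0817 for nuclear RNAs and for oxidative phosphorylation, and 0.0765 for interferon genes. It was 0.123 for p53 targets, 0.426 for the unfolded protein response, 0.0597 for cholesterol synthesis, 0.601 for heme and iron, and 0.178 for KRAB partners. With the replicate block camera called 7 more lists: cytokine targets (0.0378), nuclear RNAs (0.0485), interferon genes (0.00945), p53 targets (0.00103) and cholesterol synthesis (0.000240) higher, and DNA replication (7.09e-05) and oxidative phosphorylation (0.000240) lower. With an estimated correlation the blocked adjusted p was 0.479 for each of these 7. The camera direction and the sign of the median differed for stem cell and unfolded protein genes, and that of the mean for primary granule genes.

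The 2 guides were then set against EV separately. In the self-test each of these comparisons recovered 0 of 100 genes changed by 1 log2 unit without the block, so few calls are weak evidence of no difference. Ngp had log2 differences of -4.80 with sg2 and -3.71 with sg5, S100a8 -4.28 and -3.50, S100a9 -5.31 and -4.78, Olfm4 -1.81 and -2.67, and Cebpe -1.92 and -1.59. For sg2 against EV limma called 1 gene, the short predicted RNA Gm27974, at 17.6 and 16.8 FPKM in EV and listed at 0 in both sg2 libraries (adjusted p = 0.0406), with 150 genes at an unadjusted p under 0.05. That call was lost whenever any library was left out. With the replicate block 3 genes passed, Gm27974, Ngp (adjusted p = 0.00478) and Nmral1 (0.0116). For sg5 against EV limma called 0 genes, with 176 at an unadjusted p under 0.05, and with the block it called 2, Ngp (adjusted p = 0.0157) and Nmral1 (0.0239). Counting the library with conflicting labels as sg2 left 0 calls for both, and 2 and 0 with the block.

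No gene passed between sg5 and sg2 in limma without or with the block, with 111 and 684 genes at an unadjusted p under 0.05. Since no difference between the guides was simulated, the share of true differences that this comparison would find is not known. The difference for Cebpe was 0.33 (SE 0.43) and for Ngp 1.10 (SE 1.28). Of 28 lists, camera with the preset correlation called 5 between the guides: ribosome biogenesis lower with sg5, and glycolysis, mitosis (adjusted p = 0.0343), primary granule (0.0196) and mast cell genes higher. With the block it called 8, adding ribosomal proteins, DNA replication and oxidative phosphorylation as lower, and 0 with an estimated correlation (smallest adjusted p 0.980, and 0.554 with the block). The log2 differences of sg2 and sg5 from EV correlated across genes (Pearson r = 0.595, Spearman rho = 0.485), where genes are not independent replicates. Simulated unchanged groups with the same shared EV libraries gave 0.493 and 0.445. The covariance was 0.0815 against a simulated 0.0553. At an unadjusted p under 0.05 in the blocked fit, 151 genes were lower with both guides, against 116 in the simulation and 12.8 for independent lists. Higher with both were 111 genes, against 117 and 9.60. In the simulation the shared controls alone gave all of the excess over independent lists for higher genes, and most of it for lower genes. The 2 EV libraries are too few to split with replicates. In a check chosen after seeing the data, sg2 of number 1 and sg5 of number 2, each against the EV library of its number and thus with no library in common, gave r = 0.160 (covariance 0.0368). The reverse choice gave 0.0895 (0.0228). With the library of conflicting labels counted as sg2, r was 0.300, where sg5 is left with a library of number 1 alone, and 0.461 with the replicate block.

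**Figure D4:**
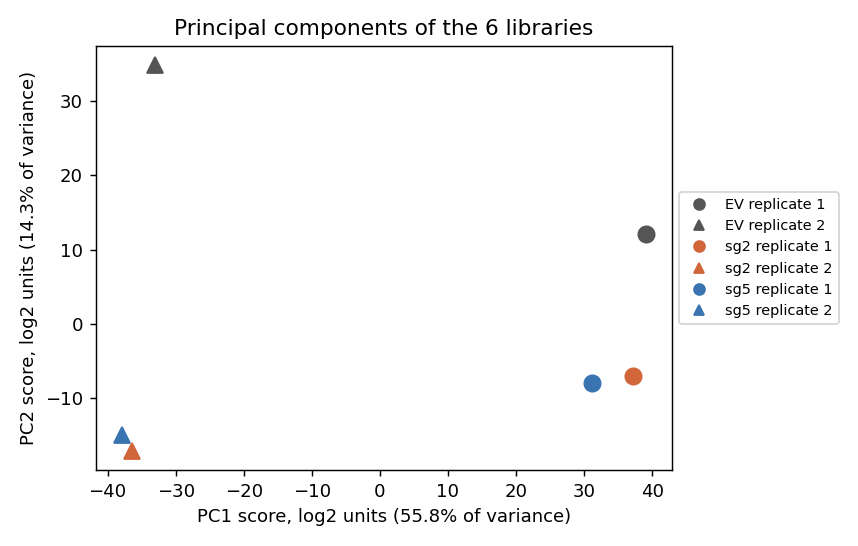
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1), in log2 units, with color for the group and marker shape for the replicate number. The first component, with 55.8% of the variance, separates replicate numbers, and the second, with 14.3%, has both EV libraries above 0 and all 4 guide libraries below 0.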

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

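The genes screened here were chosen after their values were seen. Among 41 named genes, the 4 guide libraries were screened for a library far from the others, which chance gives for about 1 in 20 groups, and 1 gene met it. Il4 in sg2 replicate 1, at 12.8 FPKM against 16.4 to 17.1 FPKM in the other guide libraries, lay apart by 0.860 of the range on the log2 scale. All 4 values were above both EV libraries.

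For 2 short or predicted RNAs the sg2 and sg5 libraries lay on opposite sides of the EV libraries. Gm20463, annotated as antisense, was listed at 0 in both sg2 libraries, at 3.09 and 4.59 FPKM in EV, and at 8.79 and 6.50 FPKM with sg5, a fitted log2 difference between guides of 3.10. Mir7052 measured 2.71 and 1.96 FPKM with sg2, 4.93 and 3.95 in EV, and 9.04 and 10.6 with sg5, a log2 difference of 1.70. Neither difference passed the limma test between guides (adjusted p = 0.435 for Gm20463 and 1.00 for Mir7052).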

How the results depend on the processing

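Alternatives with protein-coding genes only, with the block while leaving out a library or counting the conflicting library as sg2, and all but 2 of those for the correlation between guides were chosen after seeing the data. For guides against EV, 0 genes passed as planned. The count was 6 with no filter, 7 at a mean of at least 0.1 FPKM, 4 without the trend, 5 with the replicate block, 1 at an adjusted p under 0.1, 1 over protein-coding genes, and 18 over these with the replicate block. Leaving out a library, with or without the block, gave 0 to 2. For sg2 against EV, 1 gene passed, against 0 with no filter, at 0.1 or at 5 FPKM, 0 with the conflicting library as sg2 (2 with the replicate block), 2 after quantile normalization, 3 with the replicate block and 24 over protein-coding genes with it. Leaving out a library gave 0 to 0. For sg5 against EV the 0 became 18 with no filter, 23 at 0.1 FPKM, 2 with the replicate block and 33 over protein-coding genes with it. For sg5 against sg2 the 0 became 23, 20 and, over protein-coding genes with the replicate block, 3. The self-test bears on the block: it recovers more simulated changes. The cause of the other shifts was not tested.

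Cebpe stayed negative in every setting run. With all 6 libraries, a change of filter, trend, gene type, block or number of groups cannot move its log2 difference. Its value of -1.75 passed only over protein-coding genes with the replicate block (limma adjusted p = 0.0181), and the adjusted p over the other settings lay between 0.128 and 1.00. Leaving out a library gave -2.37 to -1.14, the latter without EV replicate 2.

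Of the lists, for guides against EV, 9 passed as planned, 16 with the replicate block, and 0 with an estimated correlation or with fry. Leaving out a library gave 8 to 16. Without EV replicate 1, ribosome biogenesis (adjusted p = 0.0139), DNA replication (0.00368) and oxidative phosphorylation (0.00245) turned to higher and passed, and without EV replicate 2 cholesterol synthesis turned to lower and passed (0.0141). In these fits EV holds a library of 1 number only. None of the 4 turned with the replicate block: without EV replicate 1 they were lower at 0.454, 0.00180 and 0.00493, and without EV replicate 2 cholesterol synthesis was higher at 0.272. The specific granule, mitosis and histone lists kept their direction and passed in all 16 settings with the preset correlation. The correlation between guides of 0.595 was 0.300 with the conflicting library as sg2 and 0.355 to 0.793 with a library left out. These were 0.461 and 0.444 to 0.768 with the replicate block. It was 0.160 and 0.0895 between guide differences with no library in common.

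Of 944 values for 40 other named genes, 936 kept their direction and 29 passed where the planned value had not. The 936 include values that could not turn. With all 6 libraries, a change of filter, trend, gene type, block or number of groups leaves a log2 difference as it is. Slc7a8 turned to 0.24 without EV replicate 2, the highest of its values with a library left out (lowest -1.38). Without EV replicate 1, Slc7a7 turned to -0.15 (-0.04 with the block; highest 0.69) and Prss34, a basophil protease gene outside the rule for named genes, to -0.30 from 1.55 (highest 3.40). Without EV replicate 2, Csf2rb turned to -0.087 and Csf2rb2 to -0.073 (highest 0.906 and 1.073, without EV replicate 1). Neat1 turned to -0.43 without EV replicate 1 and -0.02 without sg5 replicate 2 (highest 0.85). Of these genes, only Slc7a7 turned with the replicate block and the same library left out. Slc7a8 had -0.06, Prss34 2.03, Csf2rb 0.36, Csf2rb2 0.49 and Neat1 0.22 and 0.19. Scaling moved the median of all genes by at most 0.0067. Count-based alternatives were not run, since the files hold FPKM. A lone EV library was assumed to vary like the other groups. Depth limits genes near 0.0944 FPKM.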

Other observations

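The replicate numbers differed far more than the groups. In a limma fit with both terms, 2780 genes were higher and 3599 lower in replicate number 2 than in number 1, of 12929. H2-Ob, an MHC class II gene, measured 6.10 ± 0.52 FPKM in number 1 and 123 ± 4.05 FPKM in number 2 (SD, n = 3 each). Eno3, the muscle enolase gene, measured 9.10 ± 1.51 and 65.1 ± 7.58 FPKM. Pfkl, which encodes a phosphofructokinase, measured 139 ± 1.60 and 31.4 ± 1.75 FPKM, and Tfrc, the transferrin receptor gene, 187 ± 13.5 and 38.1 ± 1.62 FPKM. These genes were chosen after their values were seen. In number 2, limma called 46 of 52 DNA replication genes, 55 of 66 oxidative phosphorylation genes and 26 of 30 cholesterol synthesis genes lower, and 19 of 24 p53 target genes higher. Their camera adjusted p was 8.20e-12, 2.81e-12, 6.19e-08 and 8.80e-07, and no list passed with an estimated correlation (adjusted p = 0.377 for DNA replication).

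Other granulocyte genes lay below the filter and were not tested. Of 14 specific granule genes above 0 in some library, all 4 guide libraries lay below both EV libraries for 5, above both for 1, and overlapped EV for 8. Of 13 neutrophil receptor, migration and oxidase genes, the numbers were 4, 0 and 9. The genes named next were chosen after their values were seen. Mmp9, a gelatinase gene, measured 1.81 and 1.88 FPKM in EV and between 0.0425 and 0.378 FPKM with guides. Ly6g, a neutrophil surface marker gene, measured 0.574 and 1.44 FPKM in EV and was listed at 0 in 3 of the 4 guide libraries. Dgat2, a lipid synthesis gene, measured 0.223 and 0.179 FPKM in EV and between 0.438 and 0.831 FPKM with guides. Cd177, a neutrophil surface gene, measured 0.0367 and 0.683 FPKM in EV and between 0.0301 and 0.925 FPKM with guides, and Fcnb, a granule lectin gene, 0.823 and 0.905 against 0.0319 to 1.05 FPKM. Prg3, an eosinophil granule gene, measured 0.835 and 0.213 FPKM in EV and was listed at 0 in all 4 guide libraries.

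Tests of an explanation in this part were chosen after the result was seen, save that the replicate block and estimated correlation were planned settings. Specific granule genes were lower in the guide libraries by camera with the preset correlation, but did not pass with an estimated one (adjusted p = 0.0713, and 0.298 with the block). The tables argue against EV replicate 2 as the whole source (blocked camera p = 1.33e-10 without it, with the preset correlation) and against a factor per library, since 15 of 15 members lay below the median of all genes (sign test p = 6.10e-05, genes taken as independent), with the list median at -0.56 from it (bootstrap standard error 0.44). A difference between replicate numbers shared by all groups cancels by design, so the blocked camera p of 8.52e-17 does not test it, and scaling that differs with abundance stays open, since quantile normalization moved the median of all genes by 0.0067 only and its camera p of 1.79e-19 says nothing. A guide difference that differs in size between the numbers stays open too: the median was -0.23 within number 1, with 13 of 15 members below 0 and a bootstrap standard error over members of 0.43, and -0.90 within number 2. A candidate explanation is lower Cebpe, known to act on specific granule genes, a hypothesis that these data do not test against clonal differences between transduced populations, which restoring Cebpe in guide cells would.

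The split of the libraries by replicate number was set against 2 technical explanations, with both tests chosen after the split was seen. Smooth trends in GC content and transcript length accounted for 1.51% of the variance of the mean replicate difference, over 12878 of 12929 genes, which argues against them. Over protein-coding genes rescaled to the median ratio, the lowest correlation of replicate differences between groups was 0.840. Short abundant RNAs taking fragments from all genes alike would shift log values by nearly a constant. A correlation across genes ignores such a shift, so the rescaling adds no test of it. The value shows only that replicate differences varied between genes in a way that the groups shared, which such a loss alone would not give. Composition effects that differ between genes were not tested. Library composition did split by number: Mir6236 held 5.02% to 7.61% of the summed FPKM in number 1 and 13.6% to 17.7% in number 2, and protein-coding genes 73.9% to 78.1% and 59.2% to 64.1%. A difference in culture state or library batch stays open, the labels give neither, and no biological explanation was tested.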
